A study of Mus musculus with 2 samples.

How the data were processed

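Gene expression was measured in preglomerular arterioles, the small arteries that carry blood to the glomeruli and hold the renin-producing cells at their ends, isolated from mouse kidney. RBP-J is the DNA-binding factor through which Notch receptors act on transcription. Per the labels' protocols, vessels were loaded with iron oxide by perfusion, released with collagenase and collected with a magnet, and RNA was extracted with Trizol and prepared with the Ambion WT Expression Kit for an Affymetrix array. RNA of 3 wild type animals (2 males and 1 female) was pooled on 1 array. RNA of 4 male animals lacking RBP-J in cells with a renin history (RBP-J cKO) was pooled on the other. The cKO animals carried cre at 1 Ren1d allele and a floxed RBP-J gene. All animals were 3 months old.

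The deposited log2 values come from RMA, which the submitters' processing notes name together with R 2.15.0 and limma 3.12.1 without saying what each was used for. They cover 34760 probe sets, with medians of 7.25 on the wild type array and 7.21 on the cKO array. A second deposited table holds linear intensity values that, per the file headers, the authors computed with dChip from the same arrays, for 35512 probe sets. The median intensity was 268 on the wild type array and 256 on the cKO array. The same table holds the authors' signed fold score, cKO over wild type with a minus sign where wild type was higher, and its lower and upper bounds. The confidence level of these bounds, the dChip version, the genome build and the annotation version are not given in the sources used here, so no coordinates are reported. RMA was the main processing and dChip the alternative. RMA makes the overall distributions of both arrays alike, so a shift shared by most genes would not show in these values.

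Gene names were taken from the dChip table, the table that pairs probe sets with names, and brought up to date with a RefSeq gene table of the GRCm38.p6 assembly used for names only. Of its probe sets, 18664 were named through a RefSeq accession, 1957 through a synonym and 2420 through a current symbol, 2134 kept a symbol that the gene table does not hold, and 10337 had no name. Of the named probe sets 24612 were shared by both tables, giving 22270 genes. For each of the 1323 genes with several probe sets, the probe set with the highest mean over both arrays was used. A gene counted as above the floor when its brighter array reached the median level of the named probe sets, a log2 value of 7.56. This held for 11580 genes.

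Differences are cKO minus wild type on the log2 scale. Each group has 1 array and there are no replicates, so no p-value, standard deviation between samples or test of the genotype could be given, and the number of arrays limits the precision. Pooling leaves the variation between animals unmeasured. Genes were counted as apart at a 2-fold difference. Before the data were examined, 32 gene lists were fixed for renin cells, the vessel wall, other kidney and blood cell types, pathways and sex. The median difference of a list was placed among the medians of 10000 random lists of the same size, drawn from the genes above the floor and matched on mean level in 20 bins. A list outside the middle 95% of these is said to stand apart. The percentile describes these 2 arrays and requires at least 5 members above the floor, which 25 lists had. On simulated differences over 11580 independent genes, lists of 20 members shifted by 0.3 stood apart in 94% of draws and unshifted ones in 4%. For lists of 5 members the shares were 34% and 3%, so short lists can hide a shift of that size.

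The genes named are Rbpj and Ren1, the 12 genes above the floor with the largest difference in each direction (leaving out predicted genes known by a clone or model number, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors), and up to 4 members of each list with the largest absolute difference, or all members of lists with up to 5 above the floor. This left out 3 of the genes that were at least 2-fold lower and 0 of those higher. Ren2, also set to be named, has no probe set of that name here. Acta2, Myh11, Gja5, Akr1b7, Hes1, Hey1, Vwf, Cldn5, Mrc1, Cd68, Pax5, Usp9y, Zfy1, Zfy2, Cxcl13 and Cxcl2 fall outside this rule and were chosen after their values were seen. The same holds for Hes5, Hey2, Heyl, Aqp2, Slc12a1, Slc22a8, Pck1, Irf1 and Zbp1. Some list members that this rule would name are not reported here. The alternatives were no floor, a floor at the 75th percentile, centring on the median, centring on a loess trend, the dChip values, the mean over a gene's probe sets, a 1.5-fold threshold, leaving out the sex-linked and sex-biased lists, and leaving out the top member of a list. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, with matplotlib 3.10.9 for plots.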

Results

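The series holds 2 arrays, 1 for the pooled arteriole RNA of 3 wild type mice and 1 for that of 4 RBP-J cKO mice. The design asks what the loss of RBP-J from renin cells and their descendants does to gene expression in the arterioles where these cells reside. With 1 array in each group there was no replicate against which a difference could be set, and the pools also differed in sex. Over all probe sets the RMA values of the arrays correlated at r = 0.987. Among the 11580 genes above the floor the differences had a median of 0.02 and a standard deviation across genes of 0.31 on the log2 scale.

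Ren1, which encodes renin, was 1.49-fold lower in the cKO pool, with RMA levels of 10.77 in wild type and 10.19 in cKO (probe set 10349922). In the authors' deposited table its intensity was 2655 in wild type and 1605 in cKO, a signed fold of -1.65 with bounds of -1.5 and -1.82. Ren2, the near-identical copy that 129 strains carry beside Ren1, has no probe set of its own name here, so the Ren1 value is uncertain as to which copy it reads. Cre sits at 1 Ren1d allele in the cKO animals alone. Rbpj itself, the deleted gene, read 9.0 in wild type and 9.02 in cKO (probe set 10521913), a difference of 0.02 that turned to -0.02 with the dChip values. A dimmer second Rbpj probe set read 5.93 and 5.81. Deletion is confined by design to cells with a renin history, and where these probes lie relative to the deleted part is not given in the sources used here, so Rbpj does not check the labels.

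The renin cell and juxtaglomerular list was lower as a group. Of its 13 members above the floor, Ren1 included, 11 were lower and 2 higher, with a median difference of -0.16, at percentile 0.75 of random lists. Without Ren1 the median of the other 12 was again -0.16, at percentile 0.63. Endothelial, podocyte and pericyte and mesangial genes, described below, had lower medians, of -0.46, -0.34 and -0.20, and members such as Gja5, Npr1 and Foxd1 are not specific to renin cells. The lowest after Ren1 were the gap junction gene Gjc1 at -0.54, the stromal progenitor transcription factor gene Foxd1 at -0.49 and the natriuretic peptide receptor gene Npr1 at -0.43. Gja5, which encodes the connexin 40 of renin cells, differed by -0.33. Akr1b7, an aldo-keto reductase gene expressed with renin, was below the floor, at 7.18 in wild type and 7.05 in cKO, with the opposite sign in the dChip values. Genes of cyclic AMP signalling, the pathway that drives renin transcription, did not stand apart as a list, with a median of -0.06 and 11 of 16 lower. Their largest differences were -0.33 for Pde10a, -0.27 for Pde4d, -0.25 for Adcy6 and -0.24 for Creb1.

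Genes of the Notch pathway were slightly lower in the cKO pool. Of 24 members 19 were lower, the median was -0.14 and its percentile among random lists was 0.2. The receptor genes Notch4 and Notch1 differed by -0.56 and -0.49, the Notch-modifying glycosyltransferase gene Lfng by -0.44 and the ligand gene Jag2 by -0.43. Hes1 and Hey1, target genes of Notch signalling, differed by -0.23 and -0.19. The related genes Heyl, Hes5 and Hey2 were closer to equal, at -0.10, -0.06 and -0.03. In the authors' deposited table Hey2 and Heyl had signed folds of 1.02 each. Notch1 and Notch4 are expressed in endothelium, and the endothelial list described next was lower by more than the Notch list.

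Smooth muscle genes of the arteriole wall were close to equal in both pools, while genes of the other vascular and glomerular cells were lower in the cKO pool. The contractile list had a median of -0.03, with 12 of 17 members lower, and lay inside the middle 95% of random lists at percentile 14. Acta2, encoding smooth muscle actin, differed by 0.15 and Myh11, the smooth muscle myosin heavy chain gene, by -0.16. The largest differences on that list were -0.54 for Pln, 0.34 for Tagln, -0.34 for Cald1 and -0.29 for Myl9. Ion channel and calcium handling genes of smooth muscle had a median of -0.04 with 5 of 8 lower, from -0.35 for Trpc6 to 0.23 for Kcnmb1, and also lay inside. Endothelial genes had a median of -0.46 with 16 of 18 lower. Among them were Egfl7 at -0.76, Ehd3 at -0.72, Kdr at -0.72 and Flt1 at -0.66, the last pair encoding receptors of vascular endothelial growth factor. The exceptions were Cldn5 at 0.04 and Vwf at 0.15. Podocyte genes were lower in 14 of 14 cases with a median of -0.34, including the slit diaphragm gene Nphs1 at -0.63, Synpo at -0.57, Magi2 at -0.52 and Clic5 at -0.45. Pericyte and mesangial genes had a median of -0.20 with 12 of 14 lower, led by Gata3 at -0.79, Ptn at -0.75 and Tbx3 at -0.56, with Anpep, which proximal tubule also expresses strongly, at 0.66. The endothelial and podocyte medians were at percentile 0 of random lists, and the pericyte and mesangial median at 0.04.

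**Figure D1:**
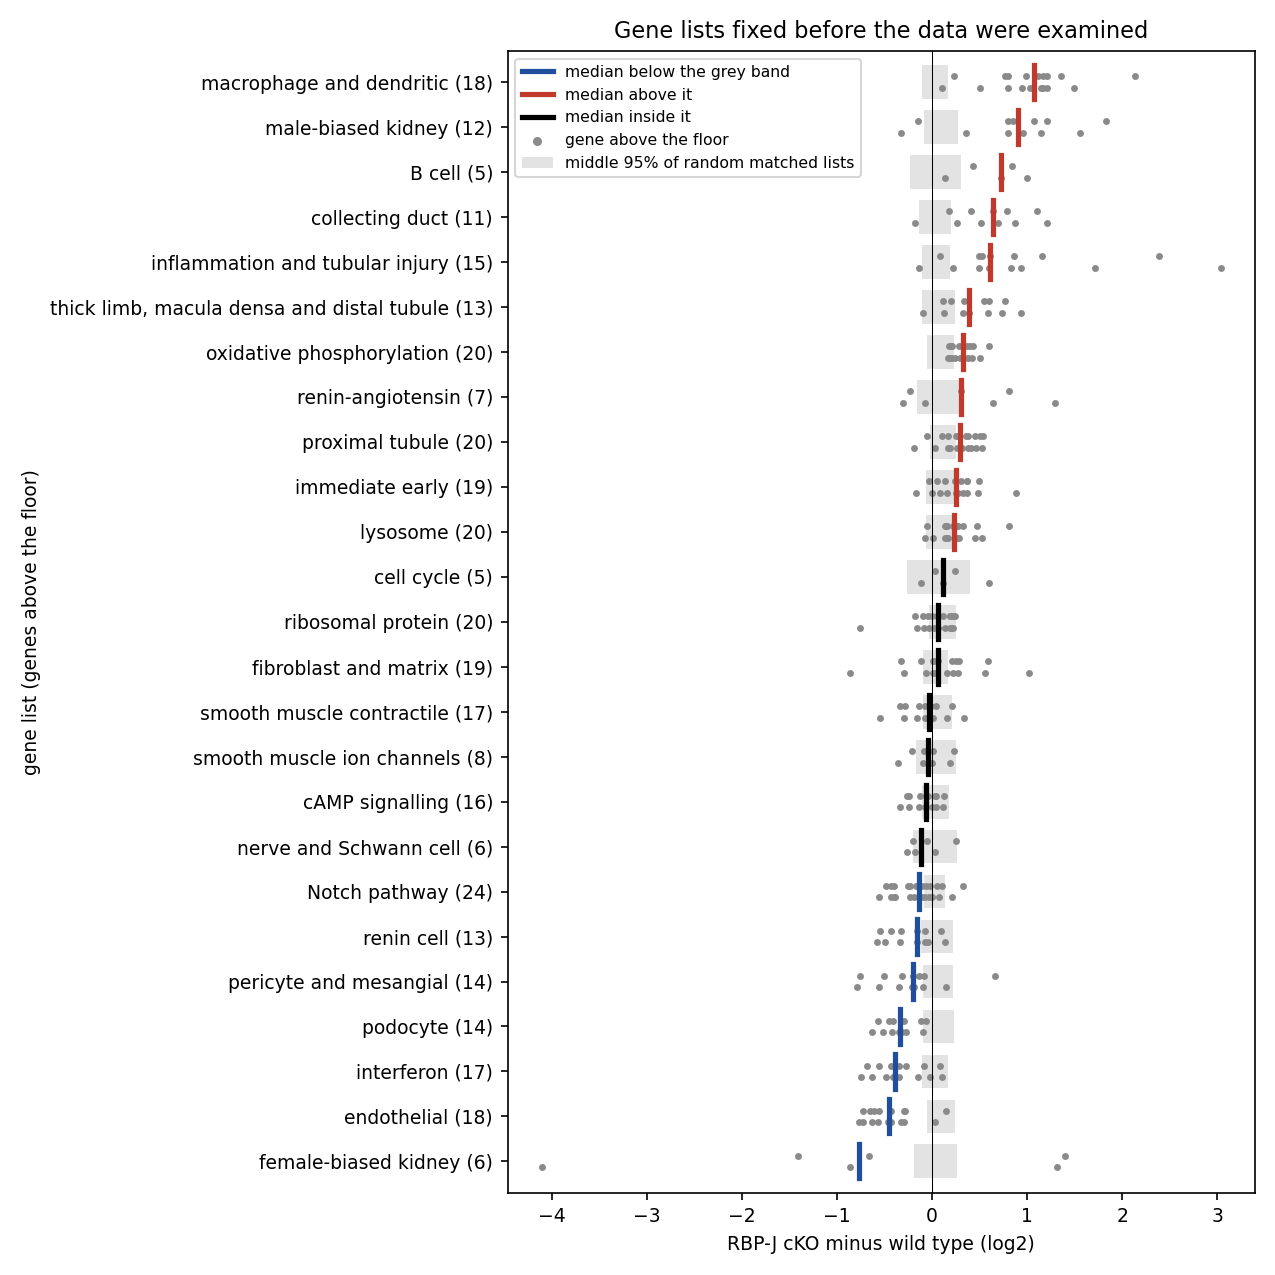
Differences between the pools (RBP-J cKO minus wild type, RMA log2) for the 25 fixed gene lists with at least 5 members above the floor. Each point is a gene, each vertical bar the list median, and each grey band the middle 95% of random lists matched on level. Macrophage and dendritic genes have the highest median, 1.07, and endothelial and podocyte genes sit at -0.46 and -0.34.

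Tubule genes were higher in the cKO pool in all 3 segments listed. Proximal tubule genes were higher in 18 of 20 cases with a median of 0.30, among them Ggt1 at 0.54, the organic anion transporter gene Slc22a6 at 0.52 and the urate transporter gene Slc22a12 at 0.50. Genes of the thick limb, macula densa and distal tubule were higher in 12 of 13 cases with a median of 0.39, led by Pvalb at 0.94, the magnesium channel gene Trpm6 at 0.77 and Cldn16 at 0.74. Collecting duct genes were higher in 10 of 11 cases with a median of 0.64. The vacuolar proton pump genes Atp6v0d2 and Atp6v1g3 of intercalated cells were higher by 1.21 and 1.11, Krt18 by 0.87 and the chloride and bicarbonate exchanger gene Slc26a4 by 0.79. The exceptions were Pck1 at -0.19 and Slc22a8 at -0.05 of proximal tubule, Slc12a1 at -0.09 of thick limb and Aqp2 at -0.18 of collecting duct. The rise was therefore not uniform within a segment. Medians of the 3 segment lists were at percentiles 99.7, 99.97 and 100 of random lists. Nuclear genes of oxidative phosphorylation, abundant in tubule cells, were higher in 20 of 20 cases with a median of 0.32, led by Ndufv1 at 0.60, Ndufa4 at 0.50 and Cox4i1 at 0.43.

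Genes of macrophages and dendritic cells had the highest median of the 25 lists with a percentile, 1.07, and were higher in the cKO pool in 18 of 18 cases, and 10 of them were at least 2-fold higher. Lyz2, encoding lysozyme, was 4.39-fold higher, with levels of 8.49 and 10.63. Adgre1, the F4/80 antigen gene, differed by 1.49, Lyz1 by 1.36 and the cathepsin S gene Ctss by 1.21. Smaller differences were seen for Cd68 at 0.51 and Mrc1 at 0.11. Genes of inflammation and tubular injury were higher in 14 of 15 cases with a median of 0.61. Lcn2, which encodes the iron-binding protein NGAL and is made by injured tubule, differed by 3.04, with levels of 6.15 in wild type and 9.19 in cKO, and by 2.39 with the dChip values. Havcr1, encoding the injury marker KIM-1, differed by 2.39, with levels of 6.45 and 8.84, and by 2.91 with the dChip values. The protease inhibitor gene Timp1 differed by 1.71, with levels of 6.80 and 8.51. The monocyte chemokine gene Ccl2 differed by 1.16. The wild type levels of Lcn2, Havcr1, Timp1, Ccl2, Adgre1, Lyz1 and Ctss lie below the floor, so the sizes of their differences are uncertain. Both list medians were at percentile 100, beside the higher tubule markers already given.

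Other blood cell lists had few members above the floor. In the B cell list 5 of 21 measured genes were above it and all 5 were higher, with Jchain at 1.00, Cd72 at 0.84, Ighm at 0.73, Blnk at 0.43 and Cd79b at 0.14, a median of 0.73 at percentile 99.97 of random lists. Without the floor the median over the 21 genes was 0.05, inside the middle 95%, and the B cell gene Pax5 was below the floor. Kit, listed with neutrophil and mast cell genes, differed by 0.68. Of the T and NK cell list, Ccl5, a chemokine gene that macrophages also express, differed by 1.68 and Cd3e by 0.18. Globin genes of red cells were higher, Hbb-b1 by 0.58, Hba-a2 by 0.23 and Hba-a1 by 0.13, while Slc25a37 differed by -0.33. Of 3 adipocyte genes above the floor Car3 was higher by 1.27, and Fabp4 and Pparg differed by -0.56 and -0.18, so their median of -0.18 and mean of 0.18 differ in sign. Actc1 was the muscle gene above the floor and differed by 0.15.

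Genes of the interferon list went the other way from the inflammation list. They were lower in 15 of 17 cases with a median of -0.38, at percentile 0 of random lists. The exceptions were Irf1 at 0.11 and Zbp1 at 0.09. The list does not hold every gene that interferon induces. The antiviral gene Rsad2 differed by -0.75, Ifit1 by -0.68, Ifi44 by -0.63 and Ifit3 by -0.56. Lysosomal genes were higher in 18 of 20 cases with a median of 0.23 (percentile 99.0), among them Cd63 at 0.53, Neu1 at 0.47 and Man2b1 at 0.45. Immediate early genes, which respond within minutes to stimuli including tissue handling, were higher in 16 of 19 cases with a median of 0.25 (percentile 98.6), led by Socs3 at 0.89, Zfp36 at 0.49 and Egr2 at 0.49. With the stricter floor their median no longer stood apart (percentile 97.2). Genes of the renin-angiotensin system other than renin had a median of 0.30 (percentile 97.9) with 4 of 7 higher. Ace, encoding angiotensin-converting enzyme, was higher by 1.29 and the angiotensinogen gene Agt by 0.80, while the peptidase gene Mme differed by -0.31. All of these are also expressed in tubule, and without Ace the list median was 0.11 and inside the middle 95%.

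Fibroblast and matrix genes did not stand apart, with a median of 0.06 and 14 of 19 higher. Their largest differences went both ways, with the fibronectin gene Fn1 at 1.02 and the periostin gene Postn at -0.86, Fbln1 at 0.59 and Mfap5 at 0.55. Ribosomal protein genes had a median of 0.06 with 12 of 20 higher, and Rpl27a was lowest at -0.75; with loess centring the median was -0.04. Nerve and Schwann cell genes had a median of -0.12 with 4 of 6 lower, among them Ngfr at -0.18, and Npy at 0.26. Of the cell cycle list 5 genes were above the floor and 4 were higher, with a median of 0.12, Ccnb2 at 0.60, Pcna at 0.24, Cdk1 at 0.12, Mcm5 at 0.03 and Mcm6 at -0.12. The signs of Ccnb2 and Mcm5 turned with the dChip values. These lists lay inside the middle 95%. In all, 11 of the 25 lists with a percentile stood above it and 7 below. Lists of unrelated genes would put 1.25 outside. Members of these lists tend to vary together and several lists share a cell source, so that number does not measure chance here.

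Sex-linked and sex-biased genes held the largest negative differences of the series. Xist, the RNA transcribed from the inactive X chromosome of females, was lower by far in the all-male cKO pool, at 11.39 in wild type and 5.41 in cKO. The Y-linked genes above the floor were higher in cKO in 4 of 4 cases, Eif2s3y by 1.16, Uty and Ddx3y by 1.01 each and Kdm5d by 0.82. Genes with higher expression in male kidney were higher in 10 of 12 cases with a median of 0.91, among them Cyp7b1 at 1.83, Slc7a13 at 1.56, Slco1a1 at 1.21 and Acsm3 at 1.15. Of 6 genes listed as female-biased 4 were lower, with a median of -0.77. Cyp4a14, a fatty acid hydroxylase gene, differed by -4.11, at 10.65 in wild type and 6.54 in cKO, and the prolactin receptor gene Prlr by -1.41, at 7.63 and 6.23. The cKO levels of Xist, Cyp4a14 and Prlr and the wild type levels of Cyp7b1 and Cyp2d9 lie below the floor, so the sizes of their differences are uncertain. Slc22a7 and Cyp2d9 on that list were higher, by 1.40 and 1.31, although Cyp2d9 is a male-predominant gene in mouse liver and its place on the list was doubtful. Both medians stood apart, at percentiles 100 and 0.

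Across the genome 99 genes were at least 2-fold higher in the cKO pool and 23 at least 2-fold lower, together 1.05% of the genes above the floor. Leaving out the sex-linked and sex-biased lists, 89 were higher and 20 lower. That step removed listed genes alone and left 11557 above the floor, so other genes that differ by sex may remain in both counts. Besides Lcn2, Havcr1 and Lyz2 described above, the genes with the largest positive differences included Aoc1, which encodes a diamine oxidase that degrades histamine, at 2.48, the class I histocompatibility gene H2-T22 at 1.89, Eddm3b at 1.81, and the circadian clock genes Arntl and Npas2 at 1.73 each. H2-T22 was higher by 0.35 with the dChip values. Immunoglobulin kappa genes closed the set, LOC100047162 at 1.70 and Igkv13-78-1 at 1.69 (1.04 with the dChip values). The wild type levels of Aoc1, H2-T22, Eddm3b, Arntl, Npas2 and these kappa genes lie below the floor, so the sizes of their differences are uncertain. Among genes lower in cKO, after Xist and Cyp4a14, were Kynu, a gene of tryptophan breakdown, at -1.88, Rdh16f2 at -1.71, the clock repressor gene Bhlhe41 at -1.57, LOC665346, named as similar to a Y-encoded testis transcript, at -1.45, and ND6, the complex I gene encoded in mitochondrial DNA, at -1.38. Csprs differed by -1.34 (-0.77 with the dChip values), Lypd1 by -1.25, the histidine decarboxylase gene Hdc by -1.24 and the hydroxyacid oxidase gene Hao2 by -1.20. The cKO levels of Kynu, LOC665346, ND6, Csprs and Hdc lie below the floor, with the same uncertainty.

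**Figure D2:**
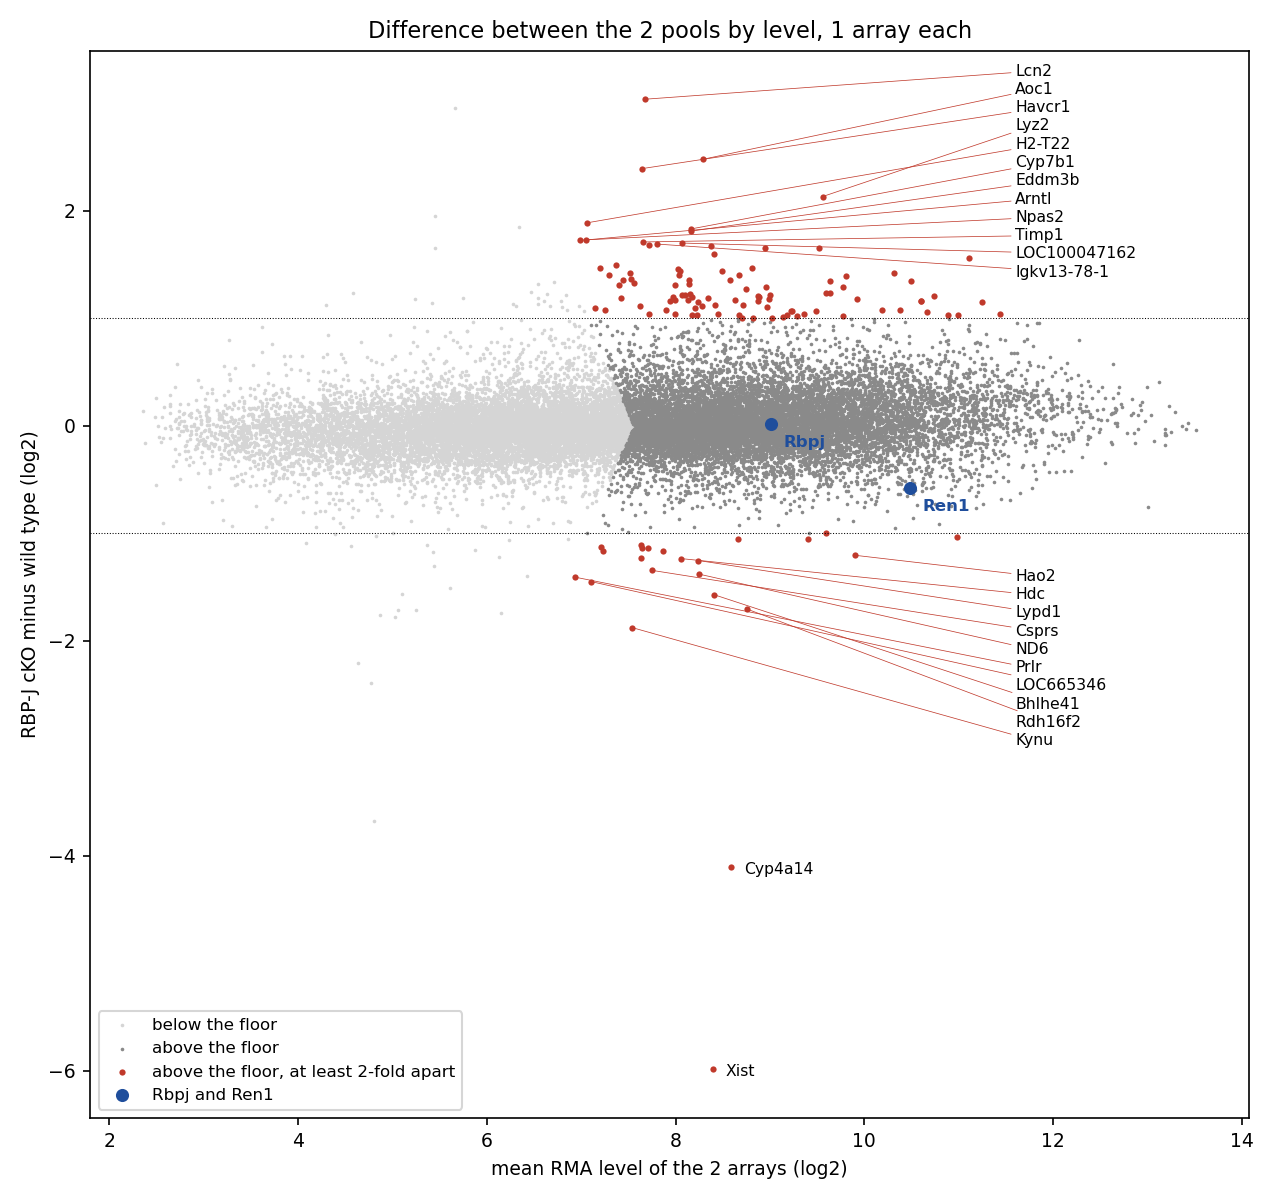
Difference between the pools (RBP-J cKO minus wild type, log2) against the mean RMA level of the 2 arrays (log2) for each of the 22270 genes. Red points are the 122 genes above the floor at least 2-fold apart, the largest 12 each way are named, and Xist at -5.99 and Cyp4a14 at -4.11 lie farthest from 0. Ren1 at -0.58 and Rbpj at 0.02 are in blue.

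The authors' other processing of the same arrays gave differences of the same sign for all 122 genes. With the dChip values 98 of them were again at least 2-fold apart in the same direction, and 117 at least 1.5-fold. Across the genes above the floor, which are not independent replicates, the RMA and dChip differences correlated at r = 0.946. In the authors' deposited table, 326 probe sets, unnamed ones included, carry the mark of their comparison filter, 153 of them higher and 173 lower in cKO.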

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

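The probe sets without a gene name were compared only after the named genes had been seen. They belong to no comparison of the report, and 8 of the 3322 above the floor were at least 2-fold higher in the cKO pool, while 41 were at least 2-fold lower. The largest of the higher ones, probe set 10538880, differed by 2.60, from 6.53 in wild type to 9.13 in cKO, with a signed fold of 5.29 in the authors' deposited table.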

How the results depend on the processing

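All alternatives for the lists fixed in advance, the threshold counts and the named genes were planned before the data were examined; those for the immunoglobulin, small nucleolar RNA, chemokine and clock lists were chosen afterwards. No called value reversed. Of the alternative values 320 kept their side of the threshold or moved by less than the spread used as a limit, 17 moved further, 5 no longer stood apart and 1 newly did. Genes at least 2-fold higher in cKO numbered 55 with the stricter floor, which tests fewer genes, and 476 at 1.5-fold, against 99. Those lower numbered 45 with no floor, 9 with the stricter floor, 13 with the dChip values and 186 at 1.5-fold, against 23. With no floor the B cell median was 0.0452 (percentile 92.0) and the renin-angiotensin median 0.11 (86.6), both no longer apart, while the cell cycle median was 0.17 over 19 genes and stood apart (99.9). With the stricter floor the renin-angiotensin median stayed at 0.30 over 5 genes and the immediate early median at 0.25, at percentiles 91.2 and 97.2, just inside the middle 95% for the latter. Without its top member Ace the renin-angiotensin median was 0.11 (74.3). The cause of these shifts was not tested beyond the genes each setting adds or removes. Among single genes, 8 differences moved with the dChip values and 3 with the mean over probe sets. The Rbpj difference, near 0 throughout, and the ribosomal protein median changed sign without standing apart. Background was not measured separately in the values used here, so how far signal below the floor stands above it is unknown, and values of dim genes such as Pax5 are uncertain. No paired analysis was possible because each group has 1 array of pooled RNA, and for the same reason no replicate could be left out.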

Other observations

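The lists in this paragraph and the next, and every test below except that of the clock genes not looked at before, were chosen after the results had been seen, and the immunoglobulin list was revised once more after its values were known. Immunoglobulin genes were higher in the cKO pool in 18 of 19 cases above the floor with a median of 1.00, and 9 were at least 2-fold higher. Without the floor, which a gene can pass by its cKO level alone, the median over 38 genes was 0.66. Among them were the light chain genes LOC100047162 at 1.70, Igkv13-78-1 at 1.69 and Iglv1 at 1.44, whose dChip intensities of 1015 and 1103 were close to each other. Such genes are transcribed at high level by antibody-secreting cells. Chemokine ligand genes were higher in 19 of 20 cases with a median of 0.64, led by Ccl5 at 1.68, Ccl9 at 1.31 (a signed fold of 3.74 in the authors' deposited table), Ccl3 at 1.23 and Ccl2 at 1.16. Cxcl2 differed by 0.93, and Cxcl13, a chemokine that attracts B cells, was the exception at -0.92. Without the floor the median over 36 chemokine genes was 0.42. Both list medians were at percentile 100 of random lists, with and without the floor.

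Small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, were lower in the cKO pool in 17 of 17 cases with a median of -0.64, at percentile 0, and Snord61, Snord87 and Snord73b differed by -0.96, -0.94 and -0.91. ND6 differed by -1.38 although the nuclear genes of oxidative phosphorylation were all higher. Clock genes split by phase. Arntl and Npas2 were higher by 1.73 each and Nfil3 by 0.74, while Clock and Cry1 were close to 0 at 0.02 and -0.09. The wild type levels of Arntl and Npas2 lie below the floor, so the sizes of their differences are uncertain. Genes expressed in the opposite phase were lower in 10 of 10 cases with a median of -0.43, among them Bhlhe41 at -1.57, Per3 at -1.0, Dbp at -0.74 and Ciart at -0.53.

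The lower Ren1 level in the cKO pool was weighed against the makeup of the preparations. A smaller share of smooth muscle in the arteriole wall is argued against by the contractile median of -0.0287. It lay 2.56 standard deviations of its members above the Ren1 difference. These deviations are a spread between genes, not an error between samples. With the dChip values the contractile median was -0.07, at percentile 3.46. Endothelial genes, also of the vessel wall, had a median of -0.46, so a smaller share of wall cells other than smooth muscle stays open. A smaller share of glomeruli with their juxtaglomerular ends stays open, since podocyte genes had a median of -0.34, 1.37 standard deviations from that of Ren1. The cre insertion at 1 Ren1d allele cannot be told apart from the deletion, because both are present in the cKO animals alone. The difference of -0.58 is smaller than the -1 that a silent allele would give if the probe set read 2 Ren1 alleles alone. Whether it also reads Ren2 is unknown, as is which animals carried Ren2. If it does read Ren2, a silent allele would give a smaller difference. A difference in Ren2 carriage between the pools was not tested. An effect of RBP-J loss on renin cells also stays open and was not tested apart from these.

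The higher macrophage and tubular injury genes were not a product of RMA, since the macrophage and dendritic median was 1.04 with the dChip values and again above the middle 95% of random lists. A larger share of macrophages in the cKO preparation stays open, since that 100% of these genes were higher restates the pattern, and Lyz2 at 2.13 and Mrc1 at 0.11 did not differ by 1 common amount. More tubule carried along stays open for Lcn2 and Havcr1, since the smaller of their differences, 2.39, exceeds the largest of 44 tubule genes, 1.21, but both were picked as the top genes of their list and are dim in wild type. Injury or inflammation in 1 or more of the pooled cKO kidneys, whether from the genotype or from a single animal, may be a source and cannot be resolved from pools.

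The sex makeup of the pools was set against the Y-linked genes. Had 3 wild type animals, 1 of them female, given equal RNA, these genes would differ by 0.58, but their mean was 1.00 (SD 0.14 across 4 genes), the value for a female share of 50% in the wild type pool. The median of the male-biased kidney genes, 0.91, was no higher than that mean. A female share of 50% would give 1.00 for a gene silent in females, and less for one that females also express. Of the 12 male-biased genes 5 were at least 2-fold higher, so the median does not decide whether female RNA accounts for the list. Several of the male-biased genes are expressed in proximal tubule, whose markers were also higher with a median of 0.30, so the tubule share stays open for part of the difference. Cyp7b1 and Slc7a13, the smaller of which differed by 1.56 against 1.16 for the highest Y-linked gene, do not decide for or against female RNA, because they were picked as the top genes of that list.

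A hypothesis for the clock genes is that the pools were collected at different times of day. If so, genes of the Per phase that had not been looked at should be lower too, and the 8 such genes were lower in 8 of 8 cases with a median of -0.39, at percentile 0. The opposite-phase genes not looked at before were not all higher, with a median of 0.02 over Nfil3, Clock and Cry1, too few for a percentile. Collection times are not given in the sources used here, and an effect of the genotype on the clock stays open.

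Probe sets of Y-encoded multi-copy testis families were mostly dim and mostly lower in the all-male cKO pool. Of 44 such probe sets, 5 of them above the floor, 37 were lower with RMA (median -0.55) and 42 with dChip (median -1.32), and the sizes are uncertain at such levels. The single-copy Y-linked genes below the floor, Usp9y, Zfy1 and Zfy2, differed by 0.08, -0.13 and 0.08, with signed folds of -1.16, -2 and -1 in the authors' deposited table, unlike the 4 brighter ones, which were higher. A candidate explanation is more genomic DNA in the wild type sample, in which high copy number would give signal without transcription. In that case other silent genes should be lower as well, and without a floor the 1309 olfactory and vomeronasal receptor genes had a median of -0.14, with 984 lower, below the -0.07 to -0.05 that held the middle 95% of random lists of like level. The dChip median was -0.18. These shifts are small beside those of the Y-encoded families. Random lists of like level hold dim genes too, and the receptor genes are not independent, so this comparison does not decide. The all-male cKO pool would also hold more Y copies for the same amount of DNA, which was not weighed. A difference in Y chromosome copies between the strains of origin was not tested.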
